A study of Sus scrofa with 14 samples.

How the data were processed

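Uterus was collected at slaughter from 14 Iberian x Meishan F2 sows, an intercross of an Iberian and a Chinese breed, between days 30 and 32 of pregnancy. Per the labels' protocols, total RNA was isolated with a column kit, labelled with biotin as cRNA and hybridized to the Affymetrix porcine GeneChip, with 1 array per sow. The labels place 5 sows in the high prolificacy group and 9 in the low prolificacy group and call each a biological replicate. They do not say from which part of the uterine wall, or at what distance from a conceptus, a sample was taken.

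The deposited values are on a log2 scale and were summarised per probe set with RMA, per the submitters' processing notes; its implementation, settings and version are not given in the sources used here. RMA corrects background, makes the distribution of probe intensities equal between arrays and combines the probes of a set, so a shift shared by most transcripts of an array would be removed. The array medians lay between 5.72 and 5.84. No detection calls were used, so whether a dim probe set lay above background is not known. The labels give no array batch. The number of arrays limits the precision of every value.

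The table held 24123 probe sets, of which 124 Affymetrix controls were left out and 23999 were tested. Gene symbols came from the platform annotation, which can be old. Among the tested probe sets, 10069 had 1 symbol, 198 had several and 13732 had none there, and only those with 1 symbol were named. Symbols were looked up by gene number in the gene table of assembly Sscrofa11.1, in which 9961 of the 10069 were found and 0 symbols changed. The 10069 probe sets stood for 6765 genes. No genome build applies to the array values, and no coordinates are given.

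High minus low prolificacy was fitted for each probe set with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, default settings, two-sided, no covariate, no filter on dim probe sets). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Errors given as SE are limma's moderated standard errors, and errors given as SD are between arrays of a group.

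Gene lists were tested with camera in limma at its preset correlation of 0.01, two-sided, on 1 probe set per gene (the brightest with exactly 1 symbol). There were 21 pathway lists and 16 lists of cell type markers, written from textbook knowledge. The 33 lists with at least 5 genes on the array were tested and adjusted together, and camera with an estimated correlation and fry were run beside it. Array quality was compared with an exact two-sided permutation test over all 2002 splits of the 14 arrays into 5 and 9. The measures were the array median, the interquartile range, the first 2 principal components and the 3-prime minus 5-prime difference of 9 porcine control transcripts, adjusted over these 13 measures.

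The named genes followed a rule. It took the 12 higher and the 12 lower probe sets with 1 symbol and the smallest p, 1 per gene. From each list past 0.05 it took the 4 genes with the smallest p in the direction of the list, and from every other tested list the 1 gene with the smallest p. PGR, ESR1, ACP5, SPP1, PTGS2, RBP4, LIF and FGF7 were always taken. In the list part and the fixed part, a gene was its brightest probe set. This gave 82 genes, and a gene taken by 2 parts of the rule counted under both. Hemoglobin, SLA and pregnancy-associated glycoprotein genes have near-identical copies that can share probes. The grouping, the tests, the lists, the rule and the first set of alternatives were fixed before the data were examined.

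These alternatives were the 12000 probe sets with the highest means, cyclic loess, subtraction of array medians, array weights, the mean levels of the smooth muscle and the epithelium lists as 2 covariates, the replicate number as a block, eBayes with trend and robust settings, an adjusted p of 0.10, an unadjusted p under 0.01 with at least 1.5-fold, 1 probe set per gene, other list tests and leaving out each of the 14 arrays. After seeing the data, 5 more were added: leaving out the 2 arrays with the highest signal of the poly-A spike-in controls, that signal as a covariate, the smooth muscle mean alone as a covariate, the mean of the trophoblast and fetal membranes list as a covariate, and, for the lists, the smooth muscle and epithelium covariates together with an estimated correlation. A list mean is the average, over the genes of the list, of log2 levels centred on each gene's mean over the 14 arrays.

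The procedure was tested on simulated data with the real probe set means and spreads, independent noise and 200 changed probe sets among 23999. For high against low prolificacy, 22% of changes of 0.5 on the log2 scale were recovered, 44% of changes of 1, 94% of changes of 2 and 100% of changes of 4, with 6 false calls among 136. With the smooth muscle and epithelium covariates, 0% of changes of 0.5, 2% of changes of 1, 44% of changes of 2 and 70% of changes of 4 were recovered. In a simulation on 6765 genes, camera recovered 10 of 10 random lists shifted by 0.5 and called 0 of 10 unshifted ones. The simulated genes varied independently, which real genes do not. No pair of arrays was a duplicate: at most 0.213% of values were identical between 2 arrays.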

Results

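Transcript levels were measured in pregnant uterus of 14 Iberian x Meishan F2 sows on an Affymetrix porcine array of 24123 probe sets. The sows were at days 30 to 32 of the fifth pregnancy, and 5 were classed as highly prolific and 9 as lowly prolific. The study asked which genes are expressed differently in the uterus of sows of high and low prolificacy. Values are log2 levels, and differences are high minus low.

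Of 18 smooth muscle genes on the array, 17 fell in the high prolificacy samples (adjusted p = 0.18 with an estimated correlation for the list), and of 18 epithelium genes 8 rose (adjusted p = 0.64 with an estimated correlation). PYGM, the glycogen phosphorylase of muscle, had a log2 level of 5.16 ± 0.72 (SD, n = 5) in high and 9.69 ± 0.63 (SD, n = 9) in low prolificacy, a difference of -4.54 ± 0.34 (SE, limma adjusted p = 3.7e-05). FASN, the fatty acid synthase, had a level of 9.71 ± 0.60 (SD, n = 5) against 7.90 ± 0.32 (SD, n = 9), a difference of 1.80 ± 0.23 (SE, limma adjusted p = 0.00076). The other FASN probe sets, all dimmer, differed by -0.023, 0.50 and 0.52 and were not called. Some other named genes also had a probe set that was not called, and 0 named genes had one called in the opposite direction. In limma, 1885 of 23999 probe sets passed an adjusted p of 0.05, of which 841 were higher and 1044 lower in high prolificacy, and 5073 passed an unadjusted p of 0.05. Among the called probe sets, 463 were at least 2-fold higher and 763 at least 2-fold lower. In 608 of them the groups did not overlap. Over all 23999 tested this held for 634, where chance gives 0.0999% of probe sets tested. The called probe sets were chosen for separating the groups, so 634, and not 608, is the count to set beside that share.

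**Figure D1:**
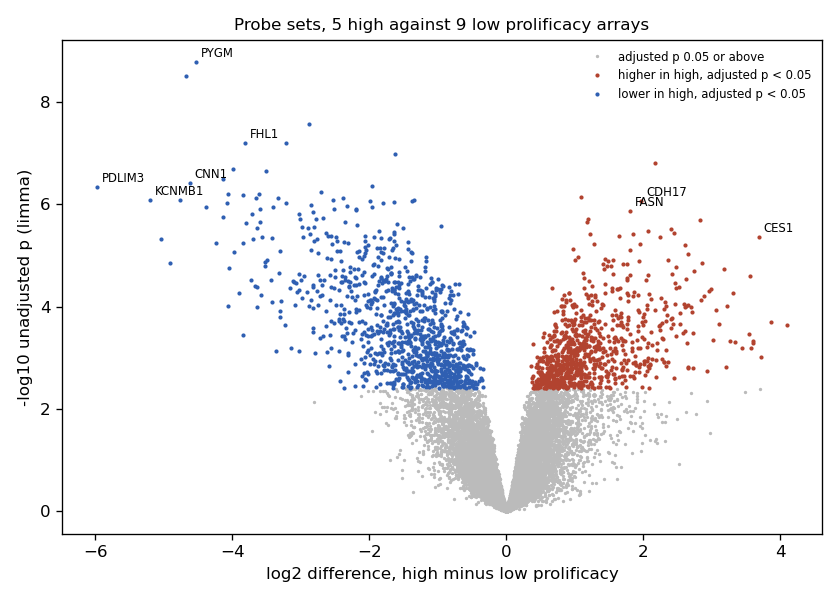
Each point is 1 of 23999 probe sets, with the log2 difference, high minus low prolificacy (5 against 9 arrays), on the x axis and -log10 of the unadjusted limma p on the y axis. Red points are the 841 probe sets called higher, blue points the 1044 called lower and grey points those not called, and PDLIM3 lies farthest to the left at -5.98.

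The 12 named genes with the smallest p among those lower in high prolificacy were PYGM, FHL1, CHPT1, DMPK, CNN1, PDLIM3, COL6A3, MCAM, TNC, MYL9, KCNMB1 and PEA15. In each of them all 5 high prolificacy arrays lay below all 9 low prolificacy arrays, and limma's adjusted p was at most 0.00072. PDLIM3, a protein of the muscle Z-disc, fell 63.2-fold, and KCNMB1, the beta subunit of the calcium-activated potassium channel of smooth muscle, fell 36.7-fold. CNN1, smooth muscle calponin, fell 24.6-fold. Without high 1 these folds were 121 for PDLIM3, 66.1 for KCNMB1 and 40.2 for CNN1. FHL1, a LIM-domain protein of muscle, fell 14.1-fold, the matrix glycoprotein TNC 14.4-fold and the collagen chain COL6A3 6.50-fold. The smallest change among the 12 was that of PEA15, at 2.54-fold.

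The 12 named genes with the smallest p among those higher in high prolificacy were CDH17, FASN, UPK3BL2, ARSE, SLC2A5, CES1, AMT, RABEPK, LGALS9, SGK2, CIAPIN1 and BZW2. In each of them all 5 high prolificacy arrays lay above all 9 low prolificacy arrays, with adjusted p from limma between 0.00072 and 0.0020. CES1, a carboxylesterase, rose 12.8-fold, from 6.12 ± 0.73 (SD, n = 9) to 9.80 ± 1.43 (SD, n = 5). ARSE, a sulfatase, rose 7.09-fold, and SLC2A5, a fructose transporter, rose 5.30-fold. CDH17, an epithelial cadherin, rose 3.91-fold, and LGALS9, galectin-9, rose 3.49-fold. The other AMT probe sets differed by 0.065 and 0.42 and were not called. SGK2 was the dimmest of the 12, at a level of 3.24 in low prolificacy, under the lowest array median of 5.72. CDH17 (4.48), UPK3BL2 (4.67), SLC2A5 (4.61), AMT (4.68) and RABEPK (4.61) also averaged under 5.72 in low prolificacy. SGK2 (4.29) and RABEPK (5.58) did so in high prolificacy too. With no detection calls, low group values of these genes may lie near background, which limits their folds.

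With the mean levels of the smooth muscle and epithelium lists as covariates, limma called 0 probe sets, with 261 at an unadjusted p under 0.05, and none of the 65 named genes that were called passed. These 2 means explained 83.4% of the group, which leaves this fit little power. In the simulation it recovered 2% of changes of 1 and 44% of changes of 2 on the log2 scale. Without high 2 the count was 1002, without high 3 it was 944 and with array weights it was 3060.

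Of 18 myometrial smooth muscle genes on the array, 17 fell and 0 rose, both over all probe sets and adjusted over the list alone, with a median log2 difference of -3.18 (camera adjusted p = 1.1e-24; adjusted p = 0.18 with an estimated correlation). MYL9, the regulatory light chain of smooth muscle myosin, was at 8.86 ± 1.10 (SD, n = 5) in high and 12.19 ± 0.57 (SD, n = 9) in low prolificacy. The remaining member, the oxytocin receptor OXTR, which was picked out after its value was seen, was at 5.96 in both groups. The list mean per array was -2.09 ± 1.17 (SD, n = 5) in high and 1.16 ± 0.41 (SD, n = 9) in low prolificacy. High 1 lay at -0.066, between the other high arrays and the low arrays.

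Of 18 uterine epithelium genes, 8 rose and 0 fell, and 14 rose when adjusted over the list alone (median difference 1.76, camera adjusted p = 4.7e-07; adjusted p = 0.64 with an estimated correlation). The keratins KRT8, KRT19 and KRT18 rose 5.55-, 5.54- and 4.83-fold, and SPINT1, an epithelial protease inhibitor, rose 4.23-fold. The epithelium list mean was 1.05 ± 0.41 (SD, n = 5) in high and -0.59 ± 1.07 (SD, n = 9) in low prolificacy, and the lowest values were those of low 7 at -2.61 and low 9 at -2.17. Of 14 stromal fibroblast genes, 4 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone (median -0.82, camera adjusted p = 0.0034; adjusted p = 0.64 with an estimated correlation). COL6A3, COL6A2, COL5A2 and the proteoglycan DCN fell, the last by 0.56 on the log2 scale. The member that rose, picked out after its value was seen, was the collagen chain COL3A1, by 1.15.

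**Figure D2:**
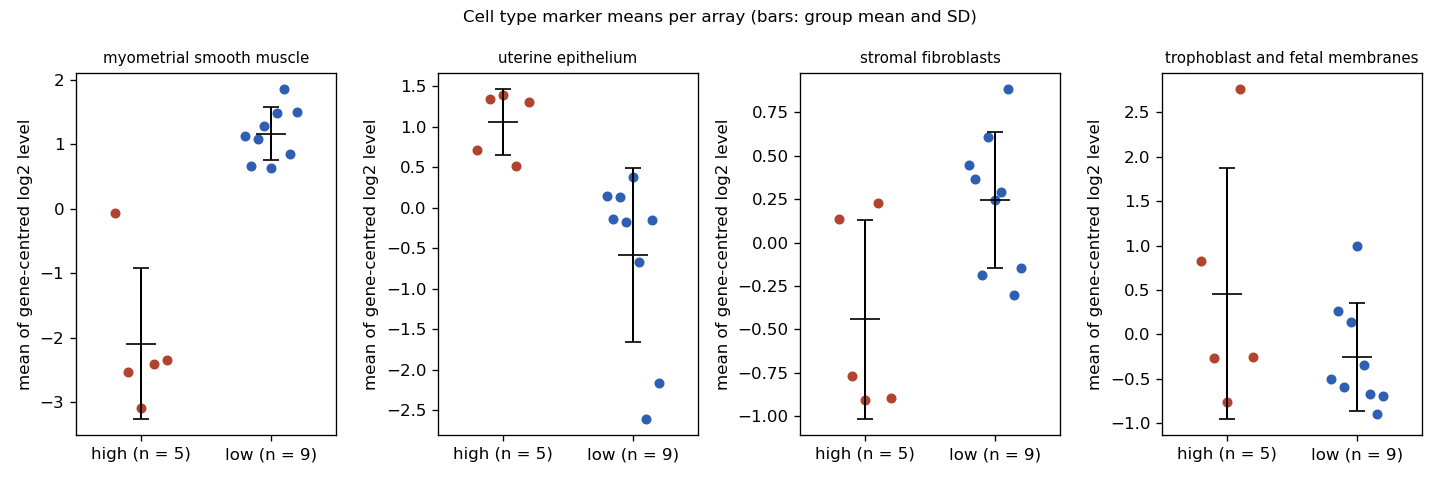
Each point is 1 array, and the y axis is the mean over the genes of a list of log2 levels centred on each gene's mean over the 14 arrays, with columns for the high (n = 5) and low (n = 9) prolificacy groups and bars at the group mean and SD. In the smooth muscle panel the high group averages -2.09 and the low group 1.16, with high 1 at -0.066, and in the trophoblast panel high 4 is the highest, at 2.75.

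Blood endothelium was not called (15 genes, median -0.31, camera adjusted p = 0.051). KDR, a receptor for vascular growth factor, rose 3.27-fold, and PECAM1, chosen after its value was seen, fell by 1.07 on the log2 scale. Nerve and glia had an adjusted p of 0.16 in camera, neutrophils 0.19, T and NK cells 0.14, macrophages and dendritic cells 0.63, B and plasma cells 0.59, red blood cells 0.65, adipocytes 0.77 and trophoblast and fetal membranes 0.24. Of their named genes, UCHL1 of nerve (-1.51), S100A9 of neutrophils (2.46) and FABP4 of adipocytes (-2.41) passed in limma. CD247 (0.58), CD86 (0.51), TNFRSF17 (0.30), HBB (-1.26) and TTR (1.12, or 0.48 without high 4) did not. Lymphatic endothelium, mast cells, mesothelium and Y-linked genes had under 5 genes on the array and were not tested. Of their members, chosen after their values were seen, LYVE1 and CCL21 of lymphatic endothelium and WT1 of mesothelium fell, KIT of mast cells rose, and neither Y-linked gene was called. DGAT2 of adipocytes, also chosen so, rose by 1.46.

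Among the pathway lists, 5 were called, all higher in high prolificacy, between the same groups in which the smooth muscle and epithelium means differed. All 5 calls were lost with array weights (camera adjusted p between 0.098 and 0.32) and with the trophoblast list mean as a covariate, an alternative chosen after seeing the data (between 0.052 for interferon response and 0.38 for cell cycle). The litter size call was also lost with the smooth muscle and epithelium covariates (0.31), and over all alternatives the adjusted p of these 5 lists lay between 0.00043 and 0.79. Members named below that lie outside the rule for named genes were chosen after their values were seen. Of 21 interferon response genes, 2 rose and 0 fell (9 rose and 1 fell adjusted over the list alone; median 0.71, camera adjusted p = 0.0034; adjusted p = 0.64 with an estimated correlation). IRF7, an interferon regulatory transcription factor, rose 1.61-fold (limma adjusted p = 0.010) and USP18, which removes ISG15 from proteins, 1.99-fold (adjusted p = 0.037). MX2 and IFI44L differed by 0.77 and 0.80, at limma adjusted p of 0.060 and 0.070. Of 21 cell cycle genes, 0 rose and 0 fell over all probe sets and over the list alone (median 0.68, camera adjusted p = 0.017; adjusted p = 0.79 with an estimated correlation). The differences of MCM3, AURKA, MCM5 and MCM2 were 0.75, 1.10, 0.68 and 0.69. The cell cycle list mean was highest in high 4, at 1.58, as was the trophoblast list mean, at 2.75. The cell cycle call was lost without high 1, high 4 or low 3 (camera adjusted p between 0.00043 and 0.25 when 1 array was left out).

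Of 23 uterine gland secretion genes, 5 rose and 0 fell (6 rose and 1 fell adjusted over the list alone; median 0.67, camera adjusted p = 0.030; adjusted p = 0.71 with an estimated correlation). The protease inhibitor CST6 rose 6.65-fold, the mucin MUC1 4.16-fold, the lysosomal activator GM2A 3.22-fold and galectin-3 (LGALS3) 2.50-fold, and UPTI differed by 2.64. Another, dimmer MUC1 probe set differed by 0.0037 and was not called. The list's call was lost without high 1, high 4, low 3 or low 9 (camera adjusted p between 0.0082 and 0.12 when 1 array was left out).

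Of 29 nutrient and ion transporter genes, 5 rose and 1 fell (8 rose and 1 fell adjusted over the list alone; median 0.47, camera adjusted p = 0.049; adjusted p = 0.71 with an estimated correlation). The calcium-binding protein S100G rose 17.2-fold, from 5.75 ± 2.02 (SD, n = 9) to 9.86 ± 0.46 (SD, n = 5). Another, dimmer S100G probe set differed by -0.62 and was not called (limma adjusted p = 0.16). The glucose transporters SLC5A1 and SLC2A3 rose 6.58-fold (10.1-fold without high 1) and 1.87-fold, and SLC2A1 rose by 1.69 on the log2 scale. The scaffold protein SLC9A3R1 rose 2.44-fold, and the water channel AQP1 fell by 0.99 on the log2 scale. The list's call was lost without high 1, high 4, high 5, low 2, low 3, low 8 or low 9 (camera adjusted p between 0.0092 and 0.11 when 1 array was left out).

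Of 32 litter size candidate genes, 5 rose and 1 fell (6 rose and 1 fell adjusted over the list alone; median 0.24, camera adjusted p = 0.038; adjusted p = 0.64 with an estimated correlation), and 15 of the 32 also stand in another list. The mucin MUC4 rose 10.1-fold, complement factor B (CFB) 3.39-fold, the nuclear receptor PPARG 3.10-fold and SLC9A3R1 2.44-fold. The prostaglandin synthase PTGS2 was at 9.73 ± 1.70 (SD, n = 5) in high and 6.01 ± 1.82 (SD, n = 9) in low prolificacy (limma adjusted p = 0.021). The progesterone receptor PGR fell by 0.84 on the log2 scale (limma adjusted p = 0.047). ESR1, ACP5, SPP1, RBP4, LIF and FGF7 were not called. Their differences were 0.67, 0.27, 1.04, 0.90, 1.36 and -0.37, and the secreted acid phosphatase ACP5 was at 13.37 ± 0.28 (SD, n = 5) and 13.10 ± 0.83 (SD, n = 9). The list's call was lost without high 1, high 4, low 3 or low 8 (camera adjusted p between 0.020 and 0.075 when 1 array was left out).

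The other pathway lists did not pass in camera, and single members of them passed in limma. In steroid metabolism (camera adjusted p = 0.064) 4 of 19 genes rose, the lipoprotein receptor SCARB1 2.68-fold beside HSD17B7, AKR1C1 and HSD11B1. In Wnt signalling (0.076) DKK3 and SFRP1 differed by -1.69 and -1.66, and in TGF-beta and activin signalling (0.14) TGFB2, TGFB3, FSTL3 and ACVR1 fell. IGF1 of the insulin-like growth factor system (0.79) fell 2.59-fold, with all 5 high arrays below all 9 low arrays, IGFBP6 fell as well and IGFBP5 rose. In prostaglandin synthesis and transport (0.75) PTGS1, PTGS2, PTGES and PTGR1 rose and the receptor PTGER3 fell by 1.58 on the log2 scale. In progesterone and estrogen signalling (0.40) PGR and NR2F2 fell. Among angiogenic factors (0.65) VEGFA, EDN1 and ADM rose and THBS2 and FGFR1 fell, and among adhesion and integrin genes (0.77) LGALS9, MUC4, ITGA2 and ITGB3 rose and ITGB1, ITGA5, FN1 and LGALS1 fell. In complement and coagulation (0.77) CFB, CFD and F3 rose and CD59, C4BPA and THBD fell. Among cytokines and inflammation genes (0.70) the chemokine CCL21 fell 6.39-fold and CCL19 fell, while CXCL14 and S100A9 rose. In hypoxia and glycolysis (0.14) HK1 and PFKL rose and PFKM fell, in mitochondrial respiration (0.14) ATP5A1 rose 1.33-fold and in antigen presentation (0.24) TAPBP rose 1.87-fold. LOXL1 of extracellular matrix remodelling (0.39) fell by 2.02 on the log2 scale. In the retinoid pathway (0.83) CYP26A1 rose and RARRES2 fell, and among immediate early and heat shock genes (0.96) MYC and HSPA5 rose and CYR61 and HSPB1 fell.

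Of 33 lists tested, 8 were called by camera, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 7 by fry, which called 5 of the same 8. The count was 4 without high 1, 5 without high 4 and 4 without low 3. In 8 lists, none of them called, the median, the mean and the direction of the test differed in sign. They were progesterone and estrogen signalling, the insulin-like growth factor system, TGF-beta and activin signalling, angiogenic factors, adhesion and integrins, complement and coagulation, immediate early and heat shock genes, and red blood cells.

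Of the 65 named genes called, 17 lost the call in at least 1 fit that left out an array. Without high 3 alone this was so of TAPBP and MUC4, without high 2 alone of TGFB2 and KDR, and without either high 2 or high 3 of MUC1 and PTGS2 (PTGS2 adjusted p between 0.0073 and 0.078). LGALS3, DKK3 and RARRES2 lost it without high 2, high 3 or high 5, SLC5A1 and UCHL1 without those or low 6, and NR2F2 without high 2, high 3, high 4 or high 5. USP18 lost it in 7 of the 14 fits (without high 1, high 3, high 4, low 6, low 7, low 8 or low 9) and PGR in 9 (without any high array, low 1, low 6, low 7 or low 9), with PGR's adjusted p between 0.030 and 0.12. ATP5A1, DCN and COL5A2 lost it in 10 each, among them those without high 2, high 3, high 5, low 1, low 2, low 6, low 7 and low 9. ATP5A1 lost it also without high 4 or low 8, DCN without low 4 or low 5, and COL5A2 without low 4 or low 8.

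Array quality was compared to see whether RNA quality or array scale moved with the groups. Of 13 measures, 1 differed past an adjusted p of 0.05, the first principal component, which held 36.3% of the variance and averaged -55.1 ± 39.0 (SD, n = 5) in high and 30.6 ± 26.7 (SD, n = 9) in low prolificacy (exact permutation adjusted p = 0.013). The adjusted p was 0.055 without high 2 and 0.055 without high 3. This component comes from the same expression values as the calls, so it is no separate sign of array quality. The array median (exact permutation adjusted p = 0.66) and interquartile range (0.97) were not called. RMA makes probe intensity distributions equal between arrays, so these 2 measures could hardly show a difference in array scale. The 3-prime minus 5-prime difference of the control Ss Actin was -0.31 ± 0.17 (SD, n = 5) in high and 0.059 ± 0.27 (SD, n = 9) in low prolificacy, with an exact permutation p of 0.020 before and 0.13 after adjustment, and the other 8 control transcripts had an adjusted p of at least 0.59.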

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

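Tests of the groups of arrays by other splits, of movement with smooth muscle within groups and of control transcript integrity were written before their results were seen; the others below were chosen after. In 282 groups of 5 or 9 arrays tested, 23 held an array far from the rest, where chance gives about 14.1. The groups tested included genes singled out after their values were seen, and genes vary together. The excess over 14.1 is thus partly built in, and no conclusion is drawn from it. High 4 held 7 of the 23, high 1 5, high 5 and low 8 3 each, low 7 2, and high 2, low 3 and low 4 1 each. Several of those in high 4 and low 8 are such singled-out genes.

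High 4 stood above the other high arrays in AHSG at 12.98, HBE1 at 12.57, CYP17A1 at 9.05, TTR at 8.44, AURKA at 8.05, the Y-linked EIF1AY at 5.86 and the Ss Angioten 3-prime minus 5-prime difference at 1.32. Of these, AHSG, HBE1, CYP17A1 and EIF1AY were singled out after their values were seen.

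High 4 had the highest level of the 14 arrays in 13 of 19 genes of the trophoblast and fetal membranes list, where 1.36 would be the share of 1 array in 14, and the sample may hold conceptus tissue. AHSG was at 12.98 there and at most 8.32 in the other arrays, AFP at 11.10 and at most 6.78, and PAG6 at 11.43 and at most 10.89, while 5 of the 19 lay above the median of at least 10 of the 14 arrays, and 3 are in another list. In high 4 the list rose by a median of 3.60 over the median of the other 13 arrays. High 4 was chosen after these values were seen, so this rise is no independent evidence. Of 10000 random lists matched on level, the median rise in high 4 was 0.021 and the highest 0.55. Genes of like level thus did not rise with the list in high 4. RMA would remove a shift shared by most transcripts, so this comparison cannot decide on array scale or RNA input. The poly-A control mean of high 4, 5.90, lay within 5.33 to 8.00 in the others. Over the 14 arrays a link of the list mean to the poly-A control signal, a measure of RNA input, stays open (Spearman rho = -0.46, permutation p = 0.097, adjusted p = 0.097; Pearson r = -0.29, permutation p = 0.30, adjusted p = 0.30; r = -0.28 without high 5 and low 3). No biological explanation was tested.

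High 1 was high among the high arrays in FHL1 at 10.53, DMPK at 8.40, FGF7 at 4.46 and the smooth muscle list mean at -0.066, and low in the Ss Gapdh 3-prime minus 5-prime difference at 0.35. ACTG2, chosen after its values were seen, was lowest among the low arrays in low 8, at 12.85.

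A probe set was counted as moving with the smooth muscle mean if their covariance within the groups was positive, however small. Over all probe sets 40.7% did so. Among 1011 probe sets called lower, members of the muscle and stromal lists left out, 98.5% moved with that mean. The highest of 100 shuffles was 96.9% and their median 50.3%. The share was 93.3% without high 1 (highest of 100 shuffles 92.9%), 93.1% in the low arrays alone (92.6%) and 93.6% in the high arrays alone, where 2 of 100 shuffles were as high, so less uterine wall muscle in the high prolificacy samples is consistent with the data. The epithelial minus the stromal marker mean was 1.49 ± 0.98 (SD, n = 5) in high and -0.83 ± 1.23 (SD, n = 9) in low prolificacy (exact permutation p = 0.0020). The 2 means thus did not shift alike, as a lower share of muscle alone, with every other cell type rising alike, would need. This comparison was chosen after epithelium was seen higher and stroma lower, so its p is no independent evidence. Uneven RNA input seen in the poly-A controls is argued against as the source of most calls. Without high 5 and low 3, 1853 probe sets were called, 1428 of them among the 1885. With the poly-A signal as a covariate 2561 were called, 1867 of them among the 1885. These counts hold probe sets of both directions. With the smooth muscle and epithelium covariates, the median difference went from -1.39 (median SE 0.29) to -0.13 (0.56) in the probe sets called lower and from 1.07 (0.25) to 0.068 (0.50) in those called higher, so the calls ended as differences shrank and errors widened, with 83.4% of the group explained by the marker means. Whether the muscle layer was thinner in these sows, was sampled less or expressed its genes less stays open, and a difference that comes with prolificacy itself is untested.

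Chance was made unlikely, but not excluded, for the count of probe sets. Among 100 splits of the 14 arrays, 1, the real one, called as many as 1885. Not every possible split was drawn, so 1 in 100 is the smallest share this test can give. The highest other split called 690 with 1 real high array in its high group, so a split unlike the real one can also call many. For the count of lists chance stays open, since 24 of 100 splits called at least 8 lists and the highest other split called 14.

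The poly-A control mean, from spike-ins added to the RNA, was 8.00 in high 5, against 5.77 to 6.04 in the other high arrays, and principal component 2 was 65.6 in high 5, while in low 3 they were 7.23 and 93.0 and in low 9 7.05 and 35.3. Over the 14 arrays this component rose with the poly-A mean by Pearson r (0.82, permutation p = 0.00095, adjusted p = 0.0057) and not by Spearman rho (0.51, permutation p = 0.064, adjusted p = 0.076), with r = 0.61 without high 5 and low 3. A group difference in RNA input stays open, since the group difference of the poly-A mean was 0.25 (exact permutation p = 0.60) with SDs of 0.96 in high and 0.72 in low prolificacy. Lower RNA integrity stays open as well: the Ss Gapdh difference had a rho of 0.54 with the poly-A mean (permutation p = 0.047, adjusted p = 0.071) and an r of 0.31 (permutation p = 0.27, adjusted p = 0.30; r = 0.53 without high 5 and low 3). These were among 6 relations computed, and no biological explanation was tested.

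Other arrays stood apart in single genes. IFI44L was 8.70 in high 5 and CFB 8.37 in high 2. Among the low arrays, COL6A3 was 12.81 and LOXL1 9.12 in low 7, PEA15 was 10.77 in low 4, and HBB was 5.78 in low 3. SLC5A1 was 5.61 and TCN1, chosen after its values were seen, 9.27 in low 8.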

How the results depend on the processing

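Of the choices, 5 were added after seeing the data: the 2 arrays of highest poly-A signal left out, that signal as a covariate, the smooth muscle mean alone and the trophoblast list mean as covariates, and the smooth muscle and epithelium covariates with an estimated correlation. The count of 1885 probe sets became 3060 with array weights, 2925 at an adjusted p of 0.10 and 877 of 6765 with 1 probe set per gene, where fewer were tested. It became 0 with the smooth muscle and epithelium covariates (261 at an unadjusted p under 0.05) and 0 with the smooth muscle covariate alone (246). Leaving out 1 array gave 944 to 2650, lowest without high 3 (1002 without high 2). The other alternatives stayed within 1.5 times, except the replicate block, described below. The count of 8 lists became 4 with array weights (3 of the same 8), 0 with an estimated correlation (2 at an unadjusted p under 0.05), 0 with the smooth muscle and epithelium covariates and an estimated correlation (3) and 5 with the trophoblast covariate (3 of the same 8, smooth muscle, epithelium and stroma), and leaving out 1 array gave 4 to 10, with 4 without high 1 or low 3 and 5 without high 4. Of the quality measures, 0 to 1 passed when 1 array was left out, and 0 without high 2 or high 3. The cause was not tested, except that the covariates follow the groups. With the replicate block, moreover, fewer arrays inform the contrast.

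Replicate numbers 1 to 5 occur in both groups. Deviations of same-numbered arrays correlated from -0.25 to 0.42, and 1 of 5 high arrays correlated best with its own number, so the numbers were not taken as pairs. With the replicate block, 35 probe sets and 6 lists were called. The remaining numbers occur only in the low group, so in this fit the arrays that bear them add nothing to the contrast. The lower count of probe sets thus comes at least partly from lost information.

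Among the 82 named genes, 65 were called and 48 were called in every fit that left out 1 array. None changed sign with cyclic loess or with array medians subtracted. USP18, DCN and COL5A2 lost the call with cyclic loess, PGR with array medians subtracted, and ATP5A1 and PGR with eBayes trend and robust settings. With the replicate block 61 of the 65 lost it, in a fit where low arrays with unshared numbers add nothing to the contrast. With the smooth muscle and epithelium covariates 51 lost their call and 14 reversed: NR2F2 0.50, PTGER3 0.10, SLC5A1 -1.15, TGFB2 0.044, DKK3 1.03, THBS2 0.55, LOXL1 0.29, CD59 0.39, ATP5A1 -0.050, CYR61 0.45, DCN 0.095, COL5A2 0.43, KDR -0.49 and UCHL1 0.31. With the smooth muscle covariate alone 48 lost it and 17 reversed: NR2F2 0.50, PTGER3 0.12, TAPBP -0.0043, SLC5A1 -1.17, TGFB2 0.097, DKK3 1.10, THBS2 0.58, LOXL1 0.36, CD59 0.40, RARRES2 0.048, ATP5A1 -0.075, CYR61 0.46, KRT18 -0.14, DCN 0.11, COL5A2 0.50, KDR -0.51 and UCHL1 0.39. None of the reversed values passed the threshold. The 2 marker means explained 83.4% of the group, and some named genes, such as CNN1 and KRT8, are members of these lists. The losses and reversals are thus partly built in and do not show that a gene was unchanged. The arrays carry no detection calls, so low signals over background limit the dimmest genes.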

Other observations

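The correlations, the permutation of list means and the estimated correlation with covariates below were chosen after the results were seen, and the covariates before. Transcripts known from the conceptus were at very different levels in arrays of both groups. PAG6, a pregnancy-associated glycoprotein of trophoblast with near-identical copies, ranged from 3.60 to 11.43 and was 10.74 in high 1, 11.43 in high 4 and 10.89 in low 4. Embryonic hemoglobin HBE1 was 12.65 in low 5, 12.57 in high 4, 10.94 in low 4 and 10.92 in low 1. AFP, the fetal albumin, was 11.10 in high 4 and 6.78 in high 1. PAG6 was not called between the groups (7.32 ± 3.56, SD, n = 5, against 6.26 ± 2.57, SD, n = 9, limma adjusted p = 0.77). PAG6, HBE1 and AFP were singled out after their values were seen.

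TCN1, a cobalamin-binding protein of secretions, also singled out after its values were seen, was 10.89 in high 2, 10.62 in high 3, 9.05 in high 5 and 9.27 in low 8, and at most 5.48 in the other 10 arrays. Its difference between the groups was 3.70 ± 1.09 (SE, limma adjusted p = 0.052).

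SPP1, a secreted adhesion protein that uterine epithelium makes in pregnancy, rose with PAG6 over the 14 arrays (Pearson r = 0.71, permutation p = 0.0056, adjusted p = 0.011; Spearman rho = 0.78, permutation p = 0.0018, adjusted p = 0.011). Within the 9 low arrays r was 0.73 (exact permutation p = 0.030, adjusted p = 0.044) and rho 0.80 (exact permutation p = 0.014, adjusted p = 0.028). Without the 2 arrays farthest from the median of PAG6, r was 0.65 over all arrays and 0.63 within the low arrays. Samples may differ in their distance from an attachment site, a hypothesis found and tested on the same data (rho = 0.78). The relation was not tested within the high arrays alone.

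With the smooth muscle and epithelium covariates, camera at its preset correlation called 8 lists, all higher in high prolificacy. They were uterine gland secretions, trophoblast and fetal membranes, interferon response, prostaglandin synthesis and transport, nutrient and ion transporters, cell cycle, complement and coagulation, and Wnt signalling, and 4 of them were also called without covariates. With an estimated correlation beside the covariates, camera called 0 lists (3 at an unadjusted p under 0.05), with adjusted p = 0.35 or more. Wnt signalling and complement and coagulation were lower in high prolificacy in the test without covariates, in which neither was called. The smooth muscle mean fell as the epithelium mean rose within the 9 low arrays (r = -0.82, exact permutation p = 0.0024, adjusted p = 0.0073; rho = -0.85, exact permutation p = 0.0061, adjusted p = 0.018; r = -0.61 without low 7 and low 5).

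Exact permutation of the list means per array, added after the data were examined, gave 9 of 33 lists past an adjusted p of 0.05. Smooth muscle and nerve and glia had the smallest (0.0082 each), and Wnt signalling (0.029), litter size candidates (0.029), epithelium (0.033), interferon response (0.044), transporters (0.044), TGF-beta and activin signalling (0.044) and neutrophils (0.044) followed. The list means of smooth muscle, nerve and glia, Wnt and TGF-beta were lower in high prolificacy, and the others higher. By camera with an estimated correlation, adjusted p was 0.71 for nerve and glia, 0.62 for Wnt, 0.64 for TGF-beta and 0.71 for neutrophils. Of the lists called by camera, gland secretions (0.077), stromal fibroblasts (0.067) and cell cycle (0.22) did not pass the permutation.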
